A study of Mus musculus with 2 samples.

How the data were processed

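The series held ChIP-seq of H3K27me3 in lung pooled from mouse embryos of the strain B6NTac;B6NCrl/Lap at 14.5 days, with both sexes in each pool. Replicate 1 was made from 24 embryos and replicate 2 from 34, and the labels number them as separate biological replicates of 1 group. A control library named in the labels was not analysed here.

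The authors deposited 4 peak lists on mm10. Per the file headers, 1 list was called on each replicate's filtered alignments, 1 on both replicates together, and the replicated list was derived from these 3. Each peak carries a signal value, the enrichment that the authors' caller gave, whose scale is not stated, so it was used within 1 list only, to rank, filter or describe peaks and to compare groups of genes. The −log10 p and −log10 q of each peak are likewise the authors' deposited values. The lists start at a −log10 p of about 2, so many peaks are weak: 47.8% of the peaks of replicate 1, 72.9% of replicate 2 and 83.8% of the replicated list have a −log10 q of at least 2. The aligner, the caller and the rule behind the replicated list are not given in the sources used here. All 21112 replicated peaks stand unchanged in the list called on both replicates together, and 12022 of them (56.9%) have at least 50% of their length under peaks of each replicate's own list. Read depth is unknown, since the lists hold no read counts, so a replicate with fewer peaks could not be told from one with fewer reads. The deposited text descriptions gave the origin of each list and no values.

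Peaks were placed on the GENCODE M21 annotation and the GRCm38 reference, the build named in the labels as mm10. From 21938 protein-coding gene records on chromosomes 1 to 19, X and Y, 21911 unique symbols were kept. The TSS was the 5' end of the gene record, and a gene was called where peaks covered at least 500 bp of the 2000 bp window around it. A window was CpG-rich with an observed over expected CpG of at least 0.6 and a GC content of at least 50%. Broad domains were peaks joined across at most 3 kb, with at least 10 kb of peak bases. Coordinates count from 1. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0 and matplotlib 3.10.9.

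Overlaps between lists and with promoters were compared with 1000 seeded circular shifts of a list within each chromosome, which keep the lengths and spacing of the peaks, as one-sided permutation tests. Shares of peaks or genes were compared by two-sided Fisher's exact tests with exact conditional 95% intervals. The 29 gene lists were adjusted together by the Benjamini-Hochberg method, against all protein-coding genes as background, with a threshold of 0.05. Chromosome X was ranked among 20 chromosomes. Medians of enrichment were compared by two-sided permutation tests with 100000 resamples, or 10000 for chromosome X, and ranks were also compared (10000 resamples) because the scale is not stated. Values with ± are the mean and SD of both replicates' own lists.

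The gene lists, thresholds, tests and alternatives were fixed before the data were examined, with the exceptions stated. The genes named were those with a TSS in the 10 domains with the most peak bases, up to 4 called and 2 uncalled members of each list by cover of the TSS window, a set of lung, lineage and housekeeping genes named in advance, and the 5 genes with the largest difference each way between replicates. Ccno, Calca, Nr5a2, Hoxa1, Hoxa4, Hoxb1, Hoxb3, Tbx2, Tbx3, Arx, Sox3, Zic3 and Pou3f4 were named after their values were seen. Chosen after seeing the data were also the alternative with 1 gene per 100 kb, the alternative with the least covered transcript start of each gene, the CpG bins, the overlap of the broad domains of both replicates, the gene families grouped by symbol and the account of domains without a coding TSS.

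The calculations were tested on simulated data. For the gene lists, 387 of 400 planted lists of 20 genes with 50% of members called, against 10% of other genes, were found (96.8%), and 4 of 400 unplanted lists passed. For replicate overlap, 1 of 40 independent pairs of 4000 simulated peaks had a permutation p under 0.05, and 30.5% of peaks were recovered as shared where 30.5% had been copied. Simulated peaks were placed at random along the chromosomes and simulated genes were called independently. These rates therefore do not cover the clustering of real peaks and genes. The alternatives covered stricter peak thresholds, the overlap that counts as shared, the list used, each replicate alone, the cover needed for a call, the choice of TSS and window, the background of the gene lists, the CpG threshold, the merge distance and peak counts in place of bases.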

Results

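Trimethylation of histone H3 at lysine 27 (H3K27me3), the mark laid down by Polycomb repressive complex 2 and found over silenced developmental genes, was mapped by chromatin immunoprecipitation and sequencing (ChIP-seq) in the lung of mouse embryos at 14.5 days. The series held 1 group of 2 biological replicates, each a pool of lungs from embryos of both sexes: 24 embryos in replicate 1 and 34 in replicate 2. At this age the airways of the mouse lung are branching and the alveoli have not formed. The deposited values were lists of peaks on mm10, so the read depth of each replicate was unknown. Replicate 1 had 44296 peaks over 20.3 Mb and replicate 2 had 48385 peaks over 25.7 Mb, a mean of 23.02 ± 3.80 Mb (SD, n = 2). The authors' replicated list, which served as the main list, had 21112 peaks over 20.7 Mb with a median length of 492 bp, and their list from both replicates together had 41112 peaks over 25.8 Mb. With no second tissue, age or treatment in the series, the comparisons were between the replicates and between parts of the genome. A gene was called where at least 500 bp of the 2000 bp around its transcription start site (TSS) lay under peaks, and cover values are the percent of that window. The enrichment given for each peak is the authors' own value and its scale is not stated, so it was used within a list only. Confidence intervals, Fisher's tests and permutation tests over genes cover counting error only, since neighbouring peaks and genes are not independent of each other.

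Both replicates marked the same large regions. Of the 257 broad domains of replicate 1, formed from its own list as described below, all shared sequence with a broad domain of replicate 2, as did 68.4% of the 374 of replicate 2 with replicate 1 (against a mean of 0.641% after random shifts, one-sided permutation p 0.001). The region with the most peak bases, over the HoxC cluster of homeobox genes on chromosome 15, held 131 ± 5.32 kb of peaks per replicate (SD, n = 2), and the HoxD region on chromosome 2 held 115 ± 4.24 kb. Around Pax3, which encodes a regulator of neural crest and muscle precursors, the replicates had 67.8 ± 5.16 kb. Of the peaks of replicate 1, 50.5% (22389 peaks) shared at least 1 base with a peak of replicate 2, against a mean of 1.70% when the other list was shifted at random along the chromosomes. Of the peaks of replicate 2, 38.0% (18369 peaks) overlapped replicate 1, against 1.53% after shifting. Both one-sided permutation p-values were 0.001, the smallest that 1000 shifts can give. The shared sequence came to 13.04 Mb, a Jaccard index (shared over combined bases) of 0.395.

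Peaks with high enrichment were almost all found again, and most weak ones were not. In the top decile of enrichment, 99.3% of the peaks of replicate 1 and 96.8% of those of replicate 2 overlapped the other replicate. In the bottom decile the shares were 31.02% and 16.5%. The odds ratio of top against bottom decile was 305 (95% exact confidence interval 215 to 450) for replicate 1 and 153 (128 to 184) for replicate 2. Against the replicated list, which was derived in part from these lists so that some overlap was built in, the shares were 99.8% and 32.3% for replicate 1, and 99.8% and 20.9% for replicate 2. Of the replicated peaks, 78.9% overlapped a peak of replicate 1 and 92.5% a peak of replicate 2.

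**Figure D1:**
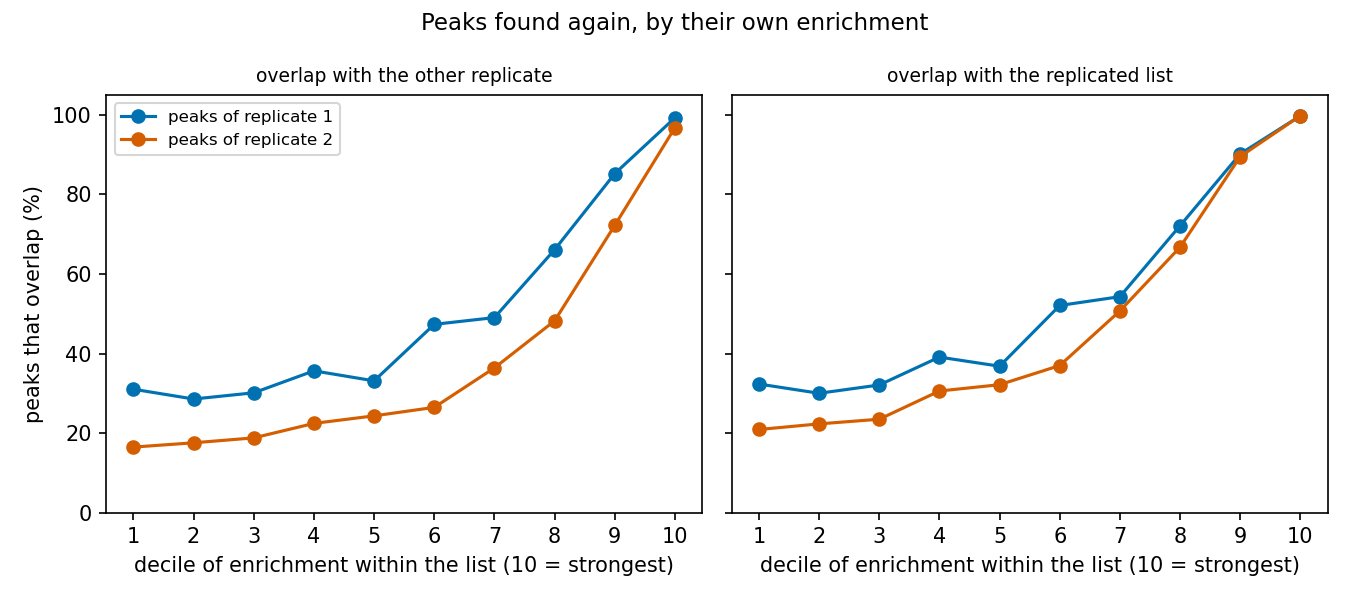
Percent of the peaks of each replicate (blue, replicate 1; orange, replicate 2) that overlapped the other replicate's list (left) or the replicated list (right), which was derived in part from both, by decile of the peak's own enrichment (10 is the strongest). The top decile reached 99.3% and 96.8% in the other replicate, and the bottom decile 31.02% and 16.5%.

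The mark was concentrated at promoters. Of the bases in replicated peaks, 19.6% lay within 1 kb of the TSS of a protein-coding gene, against a mean of 1.68% for the list shifted along the chromosomes. The ratio was 11.7 for the replicated list, 10.5 for replicate 1 and 9.74 for replicate 2, each with a one-sided permutation p of 0.001, the smallest that 1000 shifts can give. Outside promoters, 11.1% of the bases were in exons, 33.3% in introns and 35.9% between genes, where the genome has 3.26%, 35.1% and 60.0%.

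Of 21911 protein-coding genes, 2712 (12.4%) were called in the replicated list, and 2269 of these also in both replicates' own lists. Replicate 1 alone gave 2450 and replicate 2 alone 2810 (mean 2630 ± 254.6, SD, n = 2), of which 2290 were common to both. A further 160 genes were called in replicate 1 only and 520 in replicate 2 only. The largest differences towards replicate 1 were at Sqor, which encodes a mitochondrial sulfide-oxidising enzyme (74.7% of the TSS window in replicate 1 and 17.5% in replicate 2), Arvcf (70.5% and 24.3%), the chemokine gene Cxcl16 (71% and 22.0%), Nemp1 (50.9% and 0%) and Igdcc3 (49.8% and 0%). Those towards replicate 2 were at Abca17 (15.6% in replicate 1 and 100% in replicate 2), Retreg1 (4.30% and 88.9%), Spata18 (0% and 80.3%), Gnmt, which encodes glycine N-methyltransferase (10.4% and 88.4%), and Ptgfr, which encodes the prostaglandin F receptor (0% and 77.3%). These genes were picked by the size of the difference, and with 1 list per replicate the single differences could not be tested.

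Most regulators of other organs carried the mark. Among factors that pattern the central nervous system, 49 of 50 were called, and the TSS windows of 34 of them were covered completely. They included Pax6, needed for eye and forebrain (chromosome 2, TSS at 105668900), the forebrain factor Emx2, the midbrain and hindbrain boundary factor Gbx2, Gsx2 and Lhx1. The bHLH gene Neurod4 had no peak in its window. In the list of limb, craniofacial and urogenital factors, 21 of 22 were called, among them Evx1, Msx1, Pitx1 and Sall1, and Prrx2 was the exception with 0%. Cardiac factors were called in 11 of 12 cases, including Hand1, Tbx20, Irx4 and the heart regulator Nkx2-5 (96.4% ± 5.13, SD, n = 2), while Mef2c had 14.8% of its window covered. Factors of other endodermal organs were called in 16 of 19, among them the intestinal regulator Cdx2, the thyroid factor Foxe1, Onecut1, Nkx6-1 and the pancreatic regulator Pdx1 (87.5% ± 3.15, SD, n = 2). The hepatic and intestinal factors Hnf4a and Hnf1a had 0%, and Nr5a2 was also not called. However, a broad domain with 13.7 kb of peaks overlapped Nr5a2, 1.09 kb from its TSS (11.7 kb in replicate 1 and 13.6 kb in replicate 2). Somite and skeletal muscle factors were called in 12 of 17, including Pax3, Pax7, Pax9, Lbx1 and the myogenic gene Myod1 (90.9% ± 12.9, SD, n = 2). Myf5 and Meox1 had no peak of the replicated list in their windows. By Fisher's exact test (two-sided, Benjamini-Hochberg over the 29 lists), the adjusted p-values were 1.51e-42, 1.16e-17, 3.52e-09, 8.10e-12 and 9.56e-08 in the order given. These 5 lists share some members, such as Pax3 and Nkx6-1, and all 5 passed the same exact test in each replicate's own list.

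Genes that direct lung development itself were also often called. Of 23 lung epithelial regulators, 13 were called (56.5%, against 12.3% of other genes; odds ratio 9.24, 95% exact interval 3.74 to 23.6; exact adjusted p 1.10e-06). The window of Nkx2-1, the homeobox gene that specifies the lung field (chromosome 12, TSS at 56536908), was fully covered in both replicates, as was that of Sox2, a factor of the proximal airways (chromosome 3, TSS at 34650405). Foxa2, a factor of the foregut endoderm, had 99.2% ± 1.10, Irx2 86.9% ± 3.15 and the signalling gene Shh 89.7% ± 0.742 (SD, n = 2 each). Sox9, a factor of the distal tips, was not called: its window held no replicated peak, with 25.8% covered in replicate 1 and 20.4% in replicate 2, so that it was called in replicate 1 and in the list from both replicates together (25.3%) and not in the others. The epithelial factors Elf3 and Elf5 had 0% in both replicates. Of 23 lung mesenchymal regulators and signals, 15 were called (65.2%; odds ratio 13.3, 5.30 to 36.4; exact adjusted p 1.15e-08), with 10 in replicate 1, 15 in replicate 2, and 9 of the 15 in both. Called genes included Foxf1, a mesenchymal forkhead gene (81.3% ± 8.98), Tbx4 (81.3% ± 0.566), Hoxa5 (74.9% ± 9.62), Hoxb5 (58.8% ± 7.39), Wnt2 (78.5% ± 11.6) and Wnt2b (63.2% ± 24.9; SD, n = 2 each). Tbx5, which acts with Tbx4 in lung budding, was called in the replicated list with 61.6% but had 17.4% in replicate 2 (33.5% ± 22.7). The mesenchymal signal Fgf10 had 0% in both replicates, Gli3 had 0% in the replicated list, and Bmp4, with 17.2% there, differed between replicates (0% and 31.9%). The median number of peak bases within 5 kb of the TSS was 4.21 kb for called mesenchymal genes, 8.79 kb for called epithelial regulators and 9.60 kb for the called nervous system factors.

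**Figure D2:**
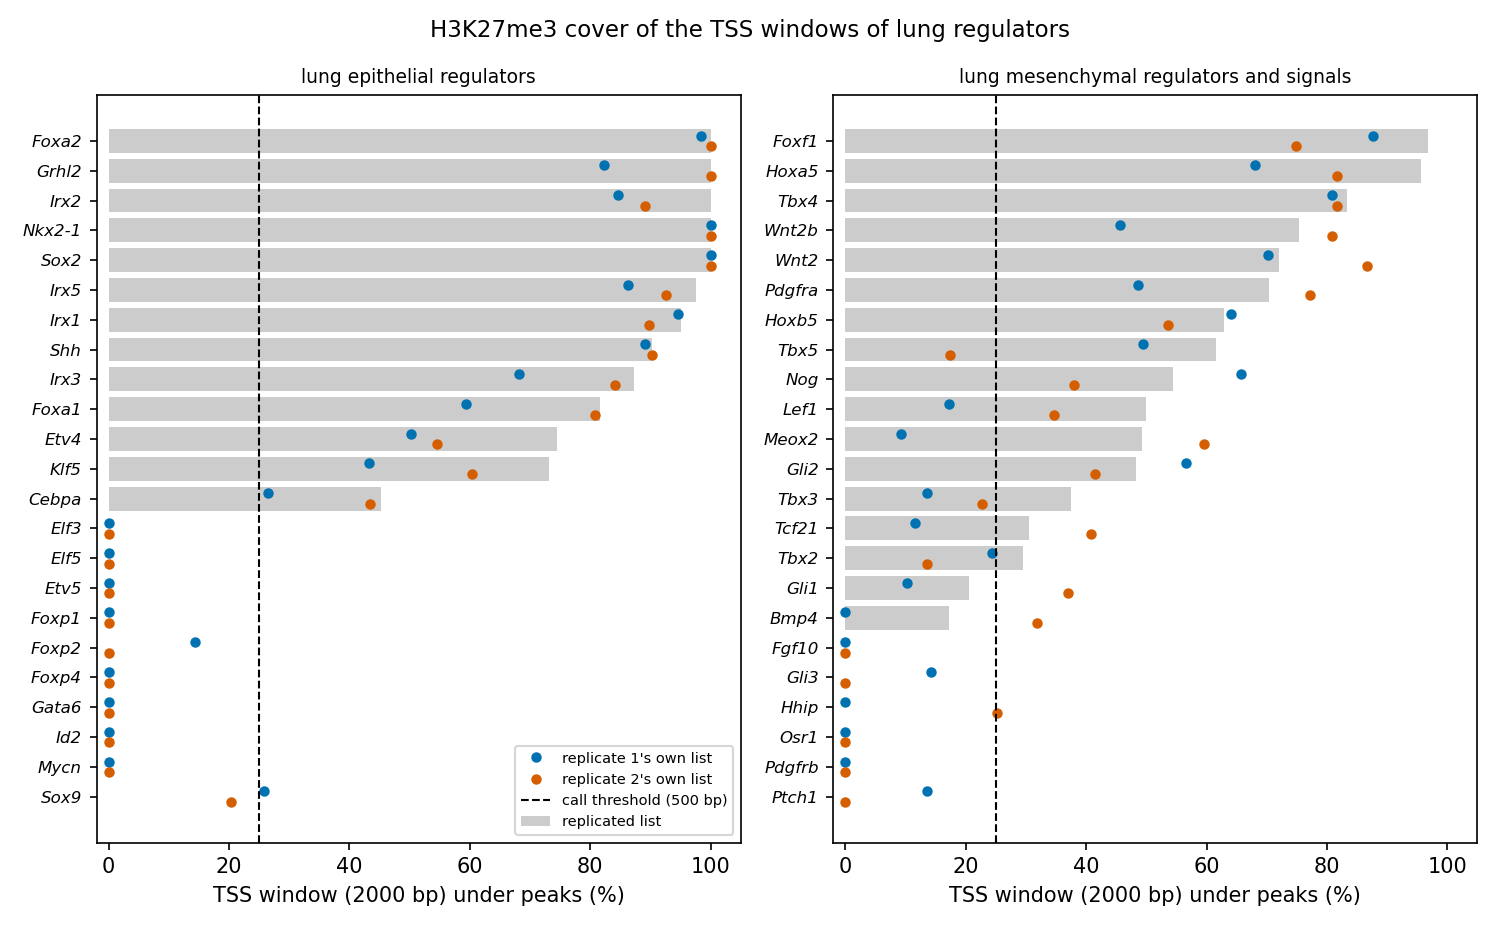
Percent of the 2000 bp TSS window under H3K27me3 peaks for the 23 lung epithelial regulators (left) and the 23 lung mesenchymal regulators and signals (right), in the replicated list (grey bars), replicate 1 (blue) and replicate 2 (orange). The dashed line is the 25% needed for a call, which 13 epithelial and 15 mesenchymal genes passed in the replicated list.

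Some markers of differentiated lung cells carried the mark and others had none. Of 21 airway markers, 7 were called (exact adjusted p 0.0154): the ciliated-cell regulators Foxj1 (49.1% ± 3.89), Mcidas (85.7% ± 8.84) and Ccno, and the neuroendocrine genes Ascl1 (93.1% ± 9.76), Insm1 (90.0% ± 7.53), Chga (78.1% ± 1.17; SD, n = 2 each) and Calca. The secretory genes Scgb1a1 and Cyp2f2 and the ciliary gene Dnah5 had no peak in their windows. This list lost its call in the replicated list when 1 bp of cover was enough (33.3%, exact adjusted p 0.0508) and when 1 gene per 100 kb was kept (31.6%, exact adjusted p 0.138). Of 20 alveolar markers, 3 were called, Aqp5 (91.1% ± 0.672), Clic5 (57.8% ± 0.601) and Abca3 (50.5% ± 52.9; SD, n = 2 each), and the exact adjusted p was 0.756. The surfactant gene Sftpc and the alveolar type 1 genes Ager and Akap5 had 0% in the replicated list. Endothelial markers were called in 7 of 20 cases (exact adjusted p 0.0121), including the transcription factors Sox7, Sox17 and Sox18 and the receptor gene Flt1 (98.7% ± 1.80, SD, n = 2), while Cdh5 and Efnb2 had 0%. Among smooth muscle and pericyte markers 4 of 12 were called (exact adjusted p 0.0706), namely Cnn1, Des, Kcnj8 and Myocd, and the contractile genes Acta2 and Actg2 had 0%. Myocd was near the limit, with 27.95% in the replicated list and 25.7% ± 3.43 over the replicates (SD, n = 2), was not called in replicate 1, and lost its call in 6 of 10 alternatives. Haematopoietic genes had 3 of 18 called (exact adjusted p 0.517), the regulators Pax5, Tal1 and Ebf1. Gata1, Alas2 and Cd19 had none of their windows covered.

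Developmental signals and transcription factor families were often marked. Wnt ligands were called in 15 of 19 cases, with Wnt1, Wnt3, Wnt10a and Wnt10b fully covered in the replicated list. Wnt5a had 8.05% covered, and Wnt11 had 20.3% with 37.5% ± 35.6 over the replicates (SD, n = 2). Fibroblast growth factors were called in 11 of 22, including Fgf3, Fgf15, Fgf16 and Fgf17 but not Fgf1, and BMP and TGF-beta ligands and antagonists in 18 of 32, including Gdf7, Bmp6, Bmp8a and Grem1 but not Bmp10 or Bmp15. T-box genes were called in 12 of 17, among them T, Eomes and Tbx15, with Mga and Tbx10 at 0%. Replicate 1 called 10 of them (exact adjusted p 5.75e-06) and replicate 2 called 9 (exact adjusted p 0.000145). Tbx2 (24.35% in replicate 1 and 13.55% in replicate 2) and Tbx3 (13.6% and 22.75%) were called in the replicated list and in neither replicate. Sox genes were called in 11 of 19, among them Sox1 and Sox14, with Sox11 and Sox12 at 0%. The exact adjusted p-values were 2.04e-10 for Wnt, 3.53e-05 for fibroblast growth factors, 1.07e-08 for BMP and TGF-beta genes, 9.56e-08 for T-box genes and 5.76e-06 for Sox genes. Pluripotency genes were called in 7 of 13 cases (exact adjusted p 0.000654), including Lin28a (87.0% ± 18.4), Tdgf1, Utf1 and Prdm14, with Dppa2 and Dppa4 at 0%. Against CpG-rich genes alone, 2 of 3 were called and the list lost its call (exact adjusted p 0.136). Imprinted genes were called in 7 of 19 cases (exact adjusted p 0.00925), including Ascl2, Phlda2 (80.3% ± 18.5), Dlk1 (55.5% ± 44.9) and Plagl1 (60.9% ± 16.5; SD, n = 2 each), with Cdkn1c and Igf2r at 0% in the replicated list. The imprinted list did not pass in replicate 1 alone (5 of 19, exact adjusted p 0.0771), nor with the least covered transcript start of each gene (3 of 19, exact adjusted p 0.481) or against CpG-rich genes (3 of 8, exact adjusted p 0.229).

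In 6 of the fixed lists no gene was called in the replicated list. They included 20 housekeeping genes, including Actb, Gapdh and Atp5b, 14 subunits of the 20S proteasome such as Psma1 and Psma2, 16 hepatocyte genes such as Afp and Ahsg, and 15 germline genes such as Dazl and Ddx4, although replicate 2 alone had 1 germline gene called. Lists of these sizes did not pass the test at 0 called (exact adjusted p 0.215, 0.276, 0.276 and 0.276). The large receptor families did pass. Of 1134 olfactory receptor genes, Olfr1 and Olfr10 among them, 0 were called (exact adjusted p 4.94e-66). Of 328 vomeronasal receptor genes, Vmn1r1 and Vmn1r10 among them, 0 were called (exact adjusted p 1.56e-18). Neither family has a CpG-rich member, and CpG content was not matched in these tests. Of 7 cyclin-dependent kinase inhibitors, the neighbours Cdkn2a (93.7% ± 4.88) and Cdkn2b (62.3% ± 14.2; SD, n = 2 each) were called and Cdkn1a and Cdkn1b had 0% (exact adjusted p 0.266). With the most covered transcript start of each gene, 4 of the 7 were called and the list passed (exact adjusted p 0.0146). Of 19 genes of the Polycomb complexes, Phf19 (47.2% ± 10.4) and Cbx8 (30.8% ± 0.530; SD, n = 2 each) were called, while Aebp2 and Bmi1 had 0% in the replicated list (exact adjusted p 1). Altogether 18 of the 29 lists were called more often than other genes, 2 less often, and 9 did not pass. Each of these 20 differences had the same direction in both replicates' own lists.

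**Figure D3:**
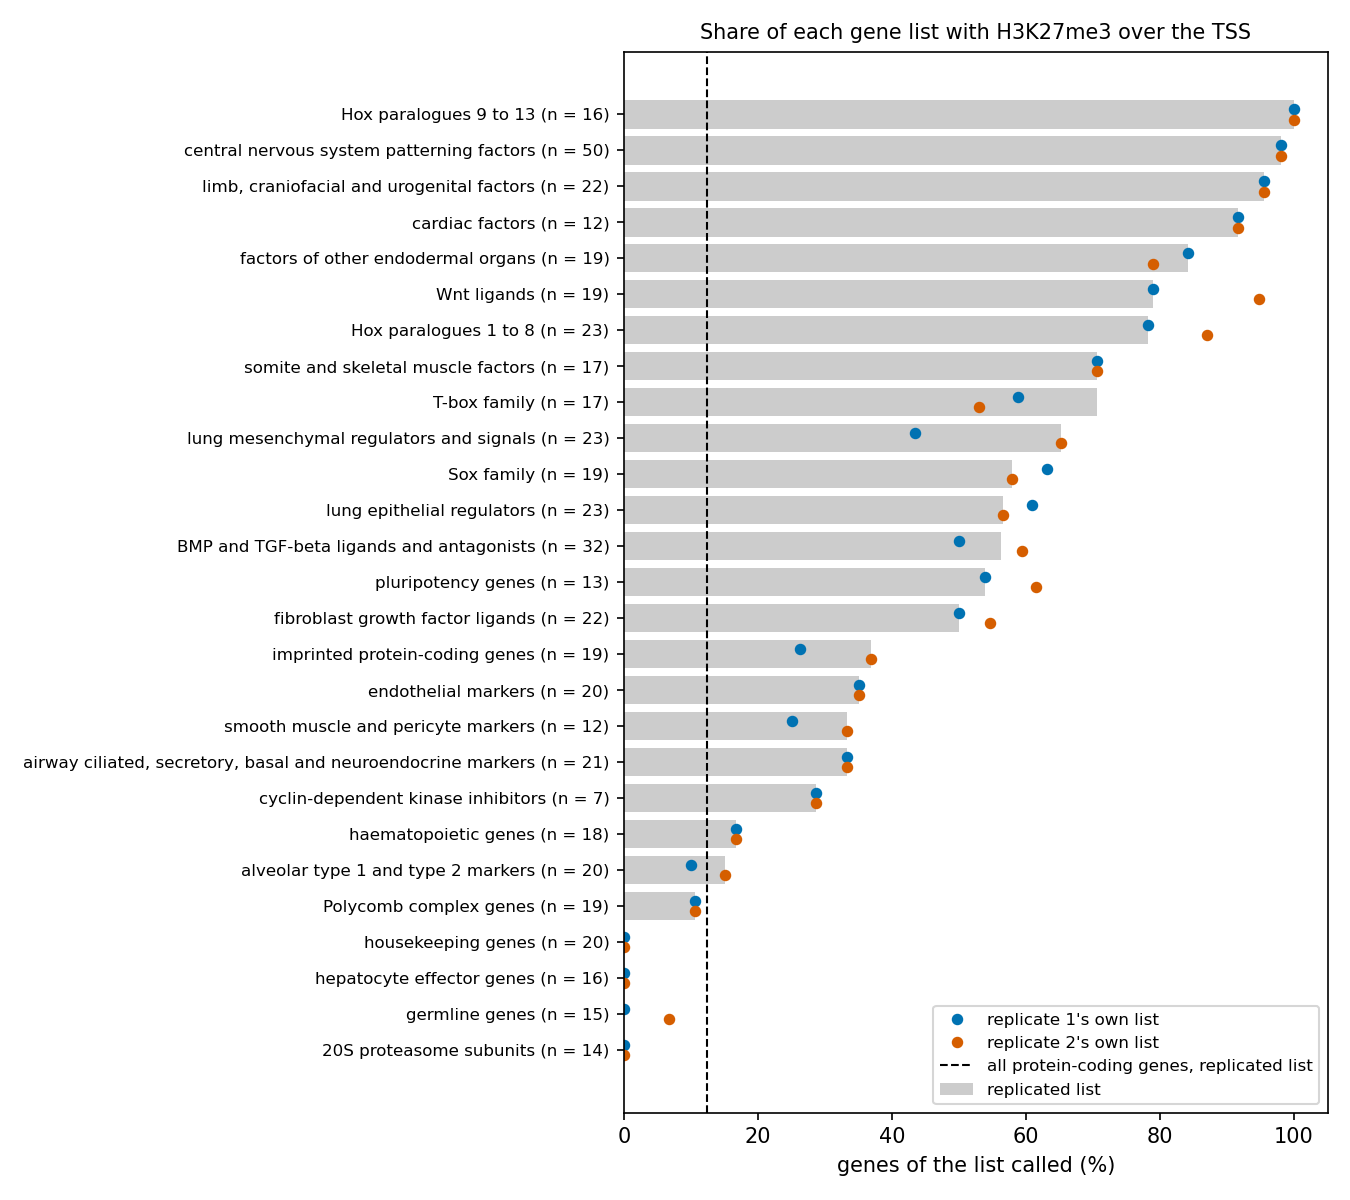
Percent of the genes of 27 fixed lists called in the replicated list (grey bars), replicate 1 (blue) and replicate 2 (orange), with the number of genes beside each list name. The dashed line is the 12.4% of all protein-coding genes, and both receptor families, with no called gene, are left out of the plot.

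The Hox clusters, whose genes set position along the body axis, carried long stretches of the mark, with gaps among the 3' genes of HoxA and HoxB and between Hoxb13 and Hoxb9. All 16 genes of paralogue groups 9 to 13 were called, among them Hoxd13 and Hoxc10, both fully covered in each replicate (exact adjusted p 1.69e-14 as a list). Of the 23 genes of groups 1 to 8, 18 were called (exact adjusted p 3.87e-12). The 5 exceptions were Hoxa2 (0% in the replicated list), Hoxa4 (13.4%), Hoxb2 (0%), Hoxb3 (14.7%) and Hoxb4 (3.50%), while all 18 genes of HoxC and HoxD were called. Some of the 5 were called in other lists. Hoxa4 had 24.85% in replicate 1 and 29.2% in replicate 2, and Hoxb3 16.15% and 40.9%, so replicate 2 called both. The list from both replicates together called Hoxa2 (37.85%) and Hoxb3 (56.1%). Hoxb4 was not called in any list, and Hoxb2 had 0% in all of them. Hoxa1, Hoxb1 and Hoxa5, in the same clusters as the exceptions, were covered over 39.4%, 91.6% and 95.6% of their windows. The difference between the groups, 78.3% against 100%, did not pass (Fisher's exact p 0.066), and with replicate 2 alone 20 of the 23 were called (exact p 0.255). Some Hox gene records begin far upstream of the gene body. The record of Hoxa3 starts beside Hoxa6, where its window was 100% covered, and its transcript start 29.5 kb away, between Hoxa2 and Hoxa4, had 31.3%. A transcript start of Hoxb3, 20.4 kb from the start of its record, was 69% covered, so that with the most covered transcript start of each gene 19 of the 23 were called.

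**Figure D4:**
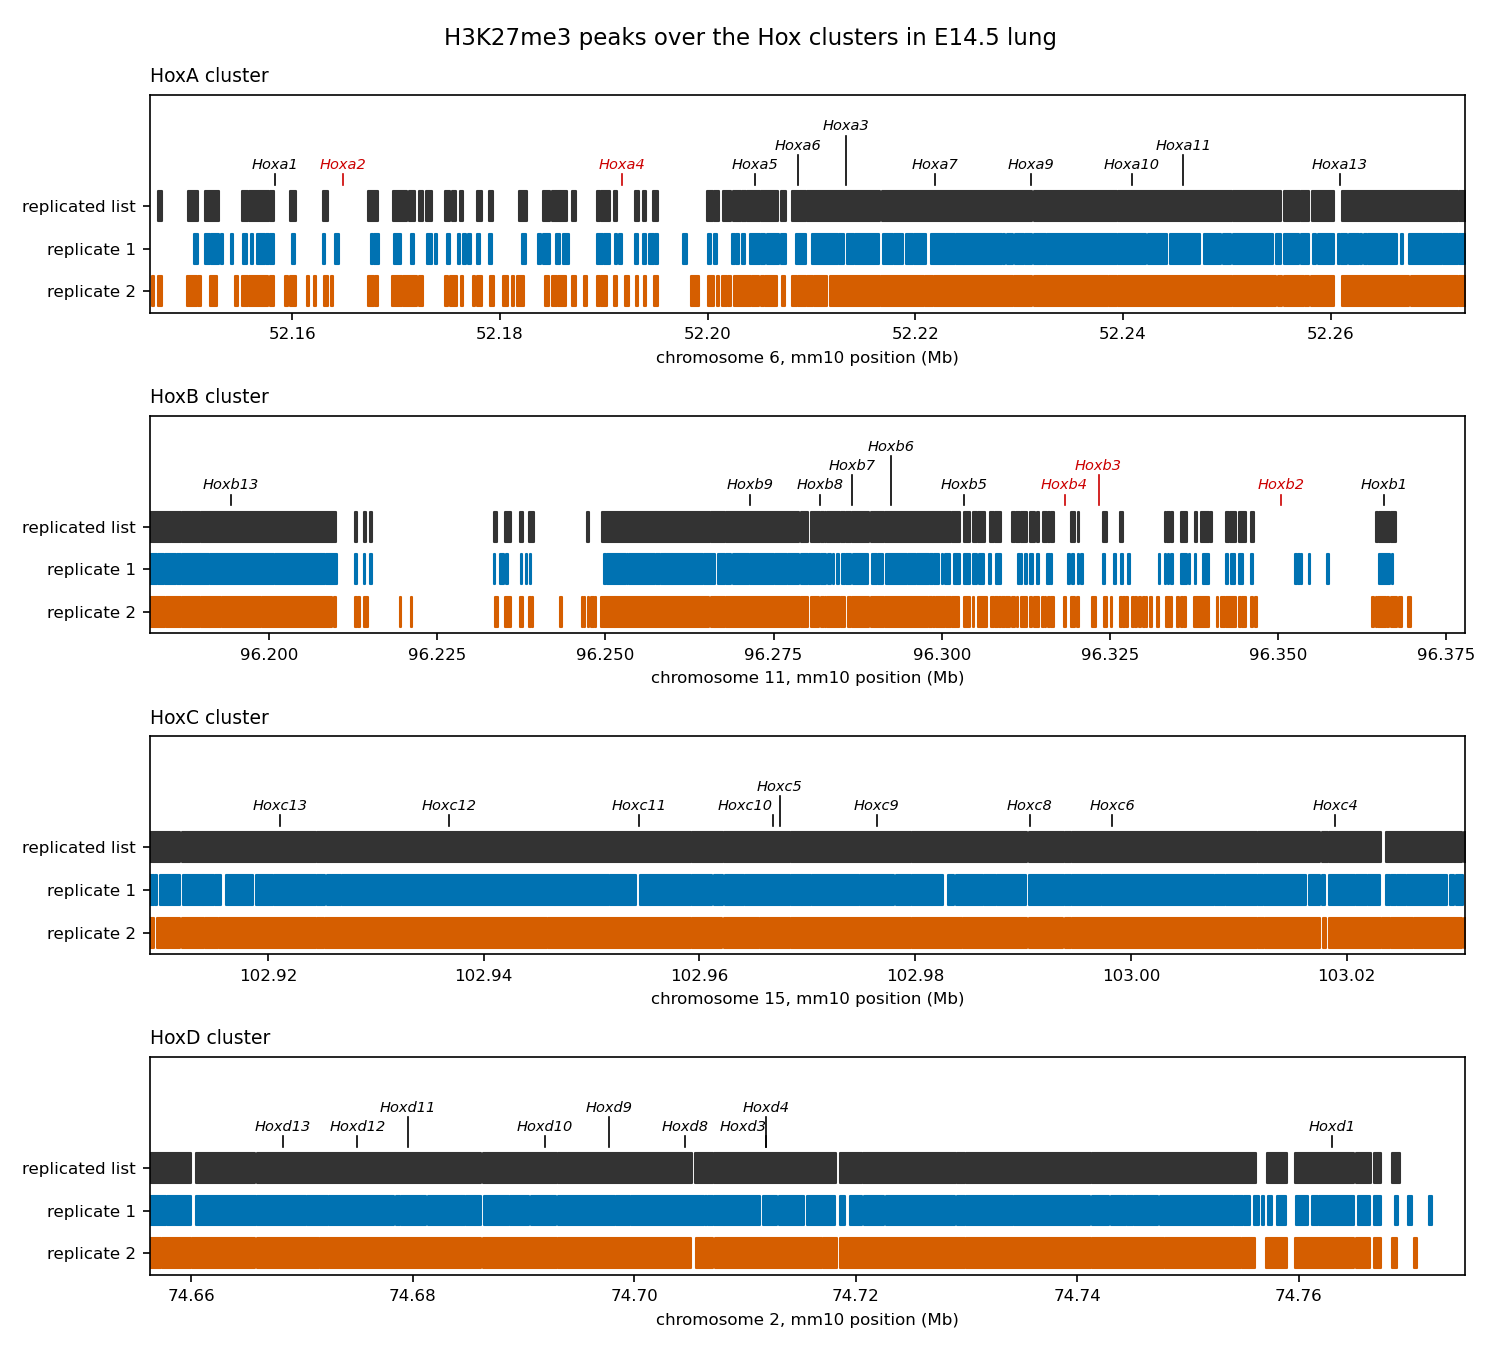
Position of H3K27me3 peaks (blocks) over the HoxA, HoxB, HoxC and HoxD clusters in the replicated list (grey), replicate 1 (blue) and replicate 2 (orange), by mm10 coordinate in Mb. Ticks mark the start of each gene record, in black where the gene was called in the replicated list and in red for the 5 that were not, all of them in HoxA and HoxB.

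CpG-rich promoters carried the mark more often than others. Of 6542 genes with a CpG-rich TSS window, 18.02% were called, among them Pax7, Emx2 and Sox2, against 9.97% of the 15369 other genes. The odds ratio was 1.98 (95% exact interval 1.83 to 2.16, Fisher's exact p 3.56e-58), with 2.12 in replicate 1 and 1.86 in replicate 2. With CpG-rich set at 0.75 of the expected CpG in place of 0.6, the odds ratio was 0.983 (exact p 0.803). In bins of CpG content chosen after the data were seen, the share called was 0.748% below 0.2 of the expected CpG (mean of replicates 0.777% ± 0.176), 22.6% from 0.4 to 0.5 (22.3% ± 2.91) and 7.23% from 0.9 upwards (7.33% ± 0.142; SD, n = 2 each).

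**Figure D5:**
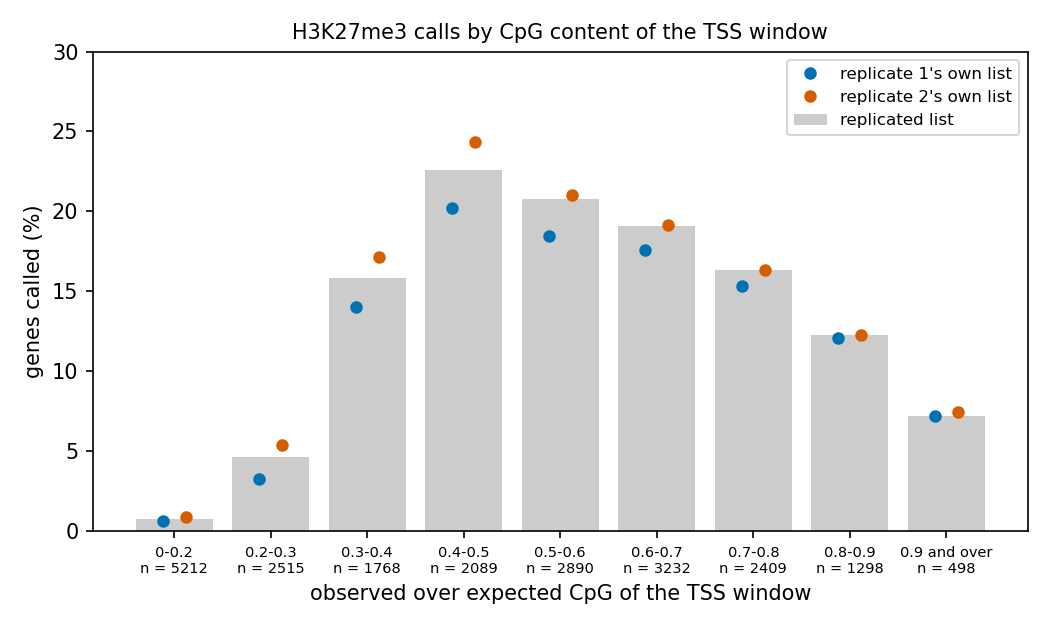
Percent of protein-coding genes called in the replicated list (grey bars), replicate 1 (blue) and replicate 2 (orange), by observed over expected CpG of the 2000 bp TSS window, with the number of genes under each bin. The share called peaked at 22.6% between 0.4 and 0.5 and was lower on both sides.

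Chromosome X, which is inactivated in 1 copy in female cells and carries this mark there, had fewer called bases than the autosomes. It held 2727 peak bases per Mb, against a median of 8537 over the 19 autosomes, whose values ran from 3724 on chromosome 16 to 14434 on chromosome 19. The ratio of 0.319 was the lowest of the 20 chromosomes, opposite to the higher cover that was the planned question, and the smallest exact rank p that 20 chromosomes allow is 0.05, one-sided. The ratio was 0.454 in replicate 1 and 0.535 in replicate 2, where chromosome 16 was lower. For peak counts in place of bases it was 0.665 in the replicated list, 0.953 in the list from both replicates together, 0.782 in replicate 1 and 1.01 in replicate 2, so by number of peaks X was not low in replicate 2. On X, 60 of 948 genes were called (6.33%), among them Arx, Sox3, Zic3, Pou3f4 and Fgf16 (91.7% ± 5.48, SD, n = 2), against 2652 of 20780 on the autosomes (12.8%).

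Broad domains, formed by joining peaks at most 3 kb apart and holding at least 10 kb of peak bases, numbered 343 in the replicated list, 257 in replicate 1 and 374 in replicate 2. They made up 32.2% of the peak bases and held the TSS of 369 protein-coding genes. Ranked by peak bases and not by span, the first ran over HoxC from Hoxc13 to Hoxc4 (chromosome 15, 102898528 to 103047119) with 137 kb of peaks. Next came HoxD with the neighbouring homeobox gene Evx2 (chromosome 2, 74642875 to 74769117; 119 kb) and HoxA from Hoxa5 to Hoxa13 (chromosome 6, 52199922 to 52281750; 75.7 kb). Pax3 lay in a domain with 75.5 kb (chromosome 1, 78132054 to 78221707), and Zic1 and Zic4, zinc finger genes of the cerebellum, in one with 66.2 kb (chromosome 9, 91347550 to 91423205). HoxB was split between a domain from Hoxb9 to Hoxb4 (chromosome 11, 96247184 to 96320476; 60.3 kb) and one around Hoxb13 (96163264 to 96215228; 46.8 kb). Hand2, which encodes a factor of heart and limb, lay in a domain with 46.1 kb (chromosome 8, 57308083 to 57357033), and Tfap2a, which encodes a neural crest factor, in one with 44.1 kb (chromosome 13, 40699667 to 40747577). The only one of the 10 domains with the most peak bases that held no protein-coding TSS was on chromosome 7 (79494172 to 79566097; 59.7 kb, with 56.1 ± 5.11 kb in the replicates, SD, n = 2).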

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

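The explanation weighed here was written down before its result was seen, but the test was changed afterwards: alternate loci and patch sequences were left out because they repeat the chromosomes by construction, and the ribosomal RNA peaks, which prompted the explanation, were no longer allowed to decide it. The test of repeated words at the other peaks was chosen only after the result was seen. The most significant peak of the replicated list lay outside the protein-coding windows that the comparisons used. It had a −log10 p of 198 at chromosome 17, 39842994 to 39846815, over an annotated ribosomal RNA gene, with an enrichment of 4.25, and the adjoining peak at 39847515 to 39848945 had 171 and 3.83. These enrichments stood at the 68.3 and 56.7 percentile of the whole list, and were low only among the 1% of peaks with the smallest p, where low meant the lowest 10% (under 10.4). Both replicates had peaks there. A candidate explanation is that reads from the many copies of the ribosomal RNA genes pile up on the single copy in the reference, which gives a very small p without the highest enrichment. Among that 1%, 9.52% of the peaks with low enrichment (2 of 21) overlapped a ribosomal RNA gene or repeated sequence, against 0 of the other 190 (Fisher's exact p 0.00948), and with alternate loci and patches included the counts were 4 of 21 and 6 of 190 (exact p 0.0104). Both positive peaks are the ones that prompted the explanation, so this count decides nothing. For the other 19, a median of 1.36% and at most 41.0% of their 32-base words were found more than once in the reference. Most of these peaks had an enrichment just under the limit (8.96 to 10.3), with at most 2.5% repeated words. For them, reads shared between copies that the reference holds are argued against. The test cannot decide for those of lower enrichment (2.96 to 7.37), split off after the values were seen. They had 8.45% to 41.0% repeated words, and the ribosomal RNA peaks themselves had at most 13.9%. Copies missing from the reference escape this search and stay open. No biological explanation was tested, since the series holds no second group.

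Of the 343 broad domains of the replicated list, 62 held no protein-coding TSS. Of these, 26 held another annotated TSS and 34 overlapped a protein-coding gene, with some domains in both sets, and 13 had neither. Only the start of 1 gene record per symbol was counted as a protein-coding TSS, so other transcript starts were not looked for. The nearest such start was 0.04 to 354 kb away, so some of these domains ended just beside a coding promoter.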

How the results depend on the processing

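The alternatives with 1 gene per 100 kb and with the least covered transcript start were chosen after seeing the data. Of 97 values other than single lists and genes, 87 kept their direction and their side of the threshold or, without a test, their size within the limits set, and so did 333 of 346 values of single lists; of 1890 calls of named genes, 36 were lost and 26 gained. A tested value that changed in size but stayed past the threshold counts as kept. With at least 50% of the peak's own length shared, the replicate overlap fell from 50.5% to 43.3% of the peaks of replicate 1. For the peaks of replicate 2 it fell from 38.0% to 27.1%. The Jaccard index of 0.395 was 0.441 with a −log10 q of at least 2, 0.479 in the stronger part of each list by enrichment (50% of its peaks) and 0.403 with equal numbers of peaks. The percent called of the alveolar list, 15%, fell below that of other genes when 1 bp was enough for a call (15%) and in replicate 1 (leave-one-out range 10% to 15%). The imprinted list lost its call in replicate 1 (leave-one-out range 26.3% to 36.8%), with the least covered start (15.8%) and against CpG-rich genes (37.5%), and the pluripotency list against CpG-rich genes (66.7%). The airway list lost it when 1 bp was enough (33.3%) and with 1 gene per 100 kb (31.6%). The Polycomb list, never past the threshold, rose above other genes when 1 bp was enough (21.1%), with the most covered start (21.1%), with the least covered start (10.5%) and with 2.5 kb windows (15.8%), and the kinase inhibitors passed with the most covered start (57.1%). Against CpG-rich genes 0 lists were called less often, because the olfactory and vomeronasal lists have no CpG-rich member and gave no value. The CpG odds ratio was 0.983 at a threshold of 0.75 (exact p 0.803), where genes of intermediate CpG content move to the other side. The X ratio of 0.319 was 0.212 in the stronger part, 0.465 in the list from both replicates together, 0.665 for peak counts (0.953 in the list from both replicates together, 0.782 in replicate 1 and 1.01 in replicate 2) and 0.454 to 0.535 with 1 replicate left out. Where no reason is given, the cause was not tested. Read depth is unknown, and whether it limits the weak peaks first could not be tested. No paired analysis was possible because the series has 1 group.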

Other observations

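The tests of gene families, the microRNA loci, the tests of enrichment of X genes, the test of X windows that are not CpG-rich and the tests by rank described here were chosen only after the data were seen. Outside the fixed lists, 20 of the gene families grouped by symbol were called more often than other genes, among them families of neuronal genes and others such as collagens and matrix metalloproteinases (Mmp, 8 of 22 called). Of 17 synaptotagmin genes (Syt), a family that includes calcium sensors of vesicle release, 13 were called (Fisher's exact test with Benjamini-Hochberg adjustment over 356 families, p 1.36e-07). The counts were 13 in replicate 1 and 14 in replicate 2. All 8 metabotropic glutamate receptor genes (Grm) were called in the replicated list and in both replicates (exact adjusted p 1.62e-06), and 11 of 14 serotonin receptor genes were called in the replicated list (Htr; 10 and 11 in the replicates, exact adjusted p 9.28e-07). Voltage-gated calcium channel genes (Cacna) were called in 9 of 14 cases (8 in each replicate, exact adjusted p 0.000134), the potassium channel genes Kcnh in 7 of 8 (7 in each replicate, exact adjusted p 6.46e-05), and collagen genes (Col) in 16 of 45 (15 and 17 in the replicates, exact adjusted p 0.000842). With the families that have members in a fixed list, 38 of the 356 were called more often than other genes and 6 less often. The Zfp family of zinc finger genes was among the last, with 13 of 394 called (11 and 14 in the replicates, exact adjusted p 2.37e-08).

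All 3 genes of the microRNA miR-9, which acts in neural development, lay in broad domains without a protein-coding TSS. Mir9-3 and its host transcript Mir9-3hg were in the domain on chromosome 7 (79494172 to 79566097; 56.1 ± 5.11 kb of peaks in the replicates, SD, n = 2). Mir9-2 was in a domain on chromosome 13 (83711438 to 83746578; 28.3 ± 1.41 kb) and Mir9-1 in one on chromosome 3 (88192827 to 88221811; 24.2 ± 4.14 kb). Another such domain on chromosome 6 (30169348 to 30182148; 11.2 ± 0.987 kb) held Mir96 and Mir183, microRNAs of sensory organs.

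Called regulators of the lung had peaks of lower enrichment than called regulators of other organs. The lung lists also hold signalling genes such as Shh and Wnt2, and the class of gene was not matched. The median of the highest enrichment in the TSS window was 5.42 for 28 called lung regulators (7.33 for the 13 epithelial and 5.04 for the 15 mesenchymal genes) and 9.16 for 103 called regulators of other organs, a difference of −3.74 in the replicated list (two-sided permutation p 1e-05, the smallest that 100000 resamples can give); by rank the lung gene was lower in 89.0% of pairs (permutation p 1e-04, the smallest that 10000 resamples can give). Lower CpG content of the lung promoters is argued against, since their median observed over expected CpG was higher, 0.707 against 0.646 for the other organs, and within 3 strata of CpG content the mean difference was −3.77 (permutation p 1e-05) and the lung gene was lower in 88.5% of pairs (permutation p 1e-04), although the smallest stratum held 7 lung genes. A mark carried by only part of the lung's cells cannot be told apart from a weaker mark in all of them: the comparison written down for it, before the enrichment values were seen but after the cover of the TSS windows, was the difference of −3.74 itself, and whole tissue cannot show which cells carry the mark.

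The low peak cover of chromosome X was set against several explanations, in the replicated list only. The X ratio was lower there (0.319) than in the list from both replicates together (0.465), replicate 1 (0.454) and replicate 2 (0.535). Why it differed between lists was not tested. More repeat-masked sequence on X is argued against as the whole cause: per Mb of unmasked sequence the ratio to the autosome median was 0.403, still the lowest of 20 chromosomes. Fewer CpG-rich promoters could contribute, since X has 0.748 of them per Mb against 2.60 on the autosomes. Of these, 17.2% were called on X (22 of 128) against 18.04% on the autosomes (Fisher's exact p 0.908, odds ratio 0.943, 95% exact interval 0.564 to 1.51). Of the other windows, 4.63% were called on X (38 of 820) against 10.4% on the autosomes (exact p 7.98e-09, odds ratio 0.418, 0.293 to 0.582). Whether fewer CpG-rich promoters are the whole cause cannot be told, because the other windows were not matched for CpG content. Over all genes the share called ran from 0.748% below 0.2 of the expected CpG to 22.6% from 0.4 to 0.5. Whether a lower copy number of X in pools of both sexes contributes to the low cover cannot be told. Enrichment could be compared only at windows already called, which shows no loss of peaks. At called CpG-rich windows the highest enrichment was lower in the X gene in 80.2% of pairs of an X and an autosomal gene (22 and 1157 genes, permutation p 1e-04, the smallest that 10000 resamples can give). This test by rank was used after the medians had been compared (4.35 against 6.47, permutation p 0.009). Any other cause of lower enrichment on X would give the same. Whether copy number keeps weak X peaks from being called cannot be told apart from lower enrichment. The X ratio of peaks per Mb was 0.0727 among the 10% of peaks with the highest enrichment and 0.747 among the rest. This was opposite to what was written down beforehand. That prediction took enrichment to be free of copy number, which the lists cannot show. Of the distinct enrichment values 99.4% go with a single p, but a value held by a single peak counts as such by itself. Peaks with an enrichment of 10.2 had a −log10 p of 42.9 and 38.6.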
